A study of Homo sapiens with 4 samples.

How the data were processed

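Polyadenylated RNA from A549 cells with NUPR1 knockdown and from control cells was sequenced as 4 libraries, 2 per group, with 1 single-end and 1 paired-end library in each group. Per the labels, RNA was extracted with Trizol and sequenced on Illumina GAIIx or HiSeq instruments. The deposited count table gives whole-number read counts for 19402 rows, with 1 column per group. The deposited RPKM table gives RPKM values with 2 decimals for 19381 of these rows, and each value above 1 equals the deposited count divided by the deposited gene length and by 1 constant per column, within 1%. TopHat2 2.0.10, edgeR 3.2.2 and the hg19 build are named per the submitters' processing notes, which give no role or order, and the tables also carry hg19 as their build. The read counter, the annotation, the strand setting, the filter on rows and the way the single-end and paired-end libraries of a group were combined are not given in the sources used here. Without strand, reads of overlapping antisense genes cannot be told apart. The sum of libraries sequenced in different layouts could weight transcripts differently in each column.

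Groups were taken from the labels. The column of the knockdown group carries a name that differs from its library titles by 1 letter and was matched by its shared start, and the level of NUPR1 is reported as a check of the labels. There were 0 further columns of values. The design fixed before the data were examined was a quasi-likelihood test on 4 libraries with the layout as a block. With 1 column per group there are 0 residual degrees of freedom, so no test was made and no p-value is given. The fallback written in that design was used, with ratios of CPM, counting intervals and gene lists set against random lists.

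In the count table, 26 gene symbols had been turned into dates and were restored from the gene description. Another 3 rows whose name or length was broken were left out, with 0.0872% of the reads in the knockdown column and 0.0509% in the control column. The remaining 19399 rows gave totals of 16635336 and 20289107 reads. Rows named by an accession, a clone or a small RNA (1351) held 8.76% and 9.84% of the reads and were kept. The 10 most abundant rows held 13.07% and 14.2%. TMM scaling and the filterByExpr filter were computed in R 4.3.3 with edgeR 4.0.16, with a minimum count of 10 and a minimum total of 15. The TMM factors were 1.01 and 0.991, and scaling by totals alone would move each log2 ratio by 0.027. A count of 0 would have been set to a floor of 3 reads, which is 0.179 CPM in the knockdown column and 0.149 CPM in the control column, and 0 of the genes with a mean of 5 CPM needed it. No pseudocount was added. Poisson intervals of counts and exact conditional (Clopper-Pearson) intervals of ratios were at 95% and were computed with scipy 1.17.1 in Python 3.11.15. Reads carry no molecular identifiers, so the intervals and the floor cover counting error only. If the mates of a pair were counted separately, which the sources do not settle, the intervals are too narrow even for that. At this depth 1 read is 0.0595 CPM or 0.0498 CPM.

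Genes were described as higher or lower by at least 2-fold when their mean was at least 5 CPM. By a rule fixed beforehand, the text names NUPR1 and SNAP25, the 10 genes with the largest ratio in each direction among those with a mean of 5 CPM, up to 4 members of each list outside its random range and up to 2 members of each other list. Genes without a symbol, microRNAs and small nucleolar RNAs were skipped, which left 3 of the higher and 4 of the lower genes out of the ranking. Some genes that this rule takes are not reported here. PTPRC, COL3A1, DCN, VWF, LUM, PDGFRB, THY1 and HBB, given by their reads as markers of other cell types, lie outside this rule.

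Before the data were examined 29 gene lists with 1194 members were fixed, and 1117 members were found in the table. The list of 13 mitochondrially encoded genes had 0 members there, which left 28 lists. For each list 10000 random lists of the same size were drawn from 20 bins of mean expression, and the percentile of the list's median among them is given. Transcript GC content came from GENCODE release 29 by gene symbol, for 88.73% of the genes measured. That annotation is on another build than the tables, so no coordinates are printed. Trends on GC content and gene length were removed as the median log2 ratio in 20 bins.

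The procedure was tested on simulated counts for the 14175 genes of the comparison, with 100 genes changed by each of 2 sizes. Counts were drawn with Poisson error alone, without variation between cultures, libraries or layouts and without correlation between genes. Genes changed by a log2 ratio of 1.5 passed the 2-fold threshold in 100% of cases and genes changed by 0.8 in 3.0%, and 0 of 10493 unchanged genes passed. The intervals held the true ratio for 95.44% of genes. These shares cover counting error only and are no error rates for a comparison of cultures. Of 200 random lists 6.0% fell outside the middle 95%. A list with 0.3 added to its computed log2 ratios had a median of 0.299, at percentile 100. That shift was added after the counts were drawn, so it tests only the ranking against random lists. Alternatives covered other scalings, other filters, RPKM with pseudocounts of 0.1 and 1, thinning to equal depth, leaving out rows without a symbol, removal of trends, other thresholds and 10 expression bins. Thinning took reads at random, in a single draw, from the control column, whose total was larger.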

Results

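The data were RNA-sequencing read counts per gene from A549 cells, an established human lung adenocarcinoma line, after knockdown of NUPR1 (also called p8, a small stress-induced chromatin protein) and from control cells. The labels list 4 libraries of polyadenylated RNA, 2 per group, of which 1 was sequenced single-end and 1 paired-end. The deposited tables hold 1 column per group, with no statement of how the libraries were combined, so there was no replicate for any value and no test of the difference between the groups. The knockdown column summed to 16649863 reads and the control column to 20299441. Levels are given as CPM, reads scaled to a common library total with TMM factors, with 95% Poisson intervals, and ratios as log2 of knockdown over control with 95% exact intervals. These intervals cover counting error only, so a difference outside them is one between these columns and not one shown to hold between the conditions.

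The comparison asked which transcripts differ in A549 cells depleted of NUPR1, and the title of the series names SNAP25 as the target of interest. NUPR1 itself was lower in the knockdown column, at 4.23 CPM (3.30 to 5.33) from 71 reads, against 9.80 CPM (8.48 to 11.3) from 197 reads in the control column. The log2 ratio of NUPR1 was -1.21 (-1.63 to -0.81), a 2.32-fold lower level, and 1.8% of the 500 genes nearest in mean expression had a lower ratio. SNAP25, a SNARE protein of vesicle fusion, had 46 reads against 295, or 2.74 CPM (2.01 to 3.65) against 14.7 CPM (13.1 to 16.5). Its log2 ratio was -2.42 (-2.90 to -1.97), a 5.36-fold lower level. Because the study named SNAP25, probably from these libraries, its low level is not independent evidence of a direction.

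KRT20, CALB2 and GDA had the highest ratios of knockdown to control, and NPTX1, GLIPR1 and CCBE1 the lowest. Of 14175 genes measured, 10689 had a mean of at least 5 CPM, and of these 106 were at least 2-fold higher in the knockdown column and 121 were at least 2-fold lower. These 227 genes were 2.12% of the 10689. The counting interval of each of the 227 excluded equal levels, which follows from the 2-fold and 5 CPM thresholds at this depth. At 1.5-fold, 398 genes were higher and 475 lower. The 5th and the 95th percentiles of the log2 ratio were -0.56 and 0.52. The counts of genes depend on the threshold and on any pseudocount added. With a minimum mean of 1 CPM 564 genes differed by 2-fold. With RPKM plus a pseudocount of 0.1 the number was 207, and with RPKM plus 1 it was 112, with SNAP25 at a log2 ratio of -1.72.

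**Figure D1:**
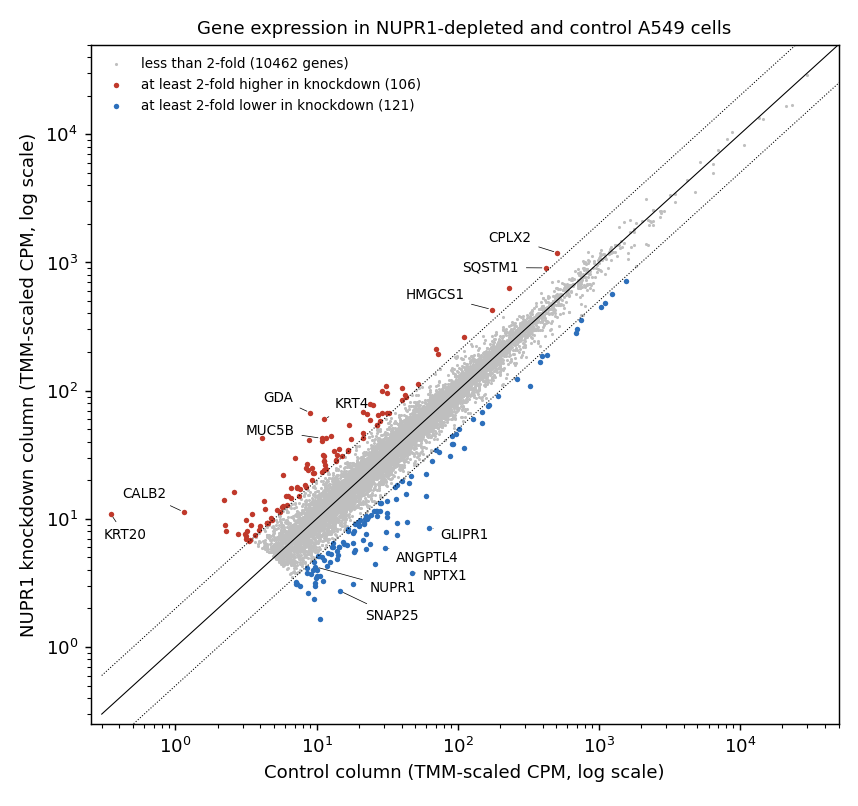
Levels of the 10689 genes with a mean of at least 5 CPM in the control column (horizontal axis, TMM-scaled CPM, log scale) and the NUPR1 knockdown column (vertical axis, same unit). The solid line marks equal levels and the dotted lines 2-fold differences; 106 genes lie above the upper line and 121 below the lower line, NUPR1 and SNAP25 among the latter.

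KRT20, a keratin of gut epithelium, was 31.3-fold higher in the knockdown column (10.9 CPM against 0.348 CPM), although its control value rested on 7 reads and the log2 interval ran from 3.90 to 6.30. CALB2, which encodes the calcium-binding protein calretinin, was 9.89-fold higher at 11.3 CPM against 1.14 CPM. GDA, which encodes guanine deaminase, was 7.47-fold higher, with 67.3 CPM (63.4 to 71.3) against 9.01 CPM (7.74 to 10.4). KRT4, a keratin of moist stratified epithelium, was 5.30-fold higher at 59.8 CPM against 11.3 CPM. LCN2, the siderophore-binding lipocalin, was 6.24-fold higher, and MGAM, a maltase of the brush border, 4.65-fold. KIAA1211L and DCDC2 were 6.42-fold and 4.24-fold higher. The gel-forming airway mucins MUC5AC and MUC5B were 4.02-fold and 3.92-fold higher, with log2 intervals of 1.52 to 2.52 and 1.75 to 2.20. These mucins are paralogs, and reads shared between them could have been split in the counting. With RPKM plus a pseudocount of 1 the log2 ratio of KRT20 was 2.59 in place of 4.97, CALB2 had 2.32, GDA 2.20, LCN2 1.95, KIAA1211L 1.59, MUC5AC 1.09 and MUC5B 1.03. The added 1 is large beside the RPKM of a long gene even when its reads are many. MUC5B, at 20243 bases, had 714 reads against 218 but an RPKM of 2.15 against 0.54.

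NPTX1, a secreted pentraxin best known from neurons, was 12.4-fold lower in the knockdown column, at 3.81 CPM (2.93 to 4.87) against 47.3 CPM (44.4 to 50.4). GLIPR1 was 7.41-fold lower at 8.52 CPM against 63.1 CPM. CCBE1, a secreted factor of lymphatic vessel growth, was 6.36-fold lower, and the adhesion molecule SDK2 5.85-fold. ANGPTL4, an inhibitor of lipoprotein lipase, was 5.15-fold lower at 5.95 CPM against 30.7 CPM. P4HA3, a subunit of collagen prolyl hydroxylase, was 5.0-fold lower, FILIP1, which binds filamin, 4.64-fold, and TNS1, a focal adhesion protein, 4.05-fold. The readthrough gene INS-IGF2 had 75 reads against 525, a log2 ratio of -2.55, but it overlaps INS and IGF2 and its assignment is uncertain. With RPKM plus 1 TNS1 was no longer 2-fold lower, at a log2 ratio of -0.55 in place of -2.02, and NPTX1 had -2.50, INS-IGF2 -1.67, CCBE1 -1.06 and SDK2 -1.02. TNS1 and SDK2 are long genes (13044 and 11431 bases), so the added 1 is large beside their RPKM.

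**Figure D2:**
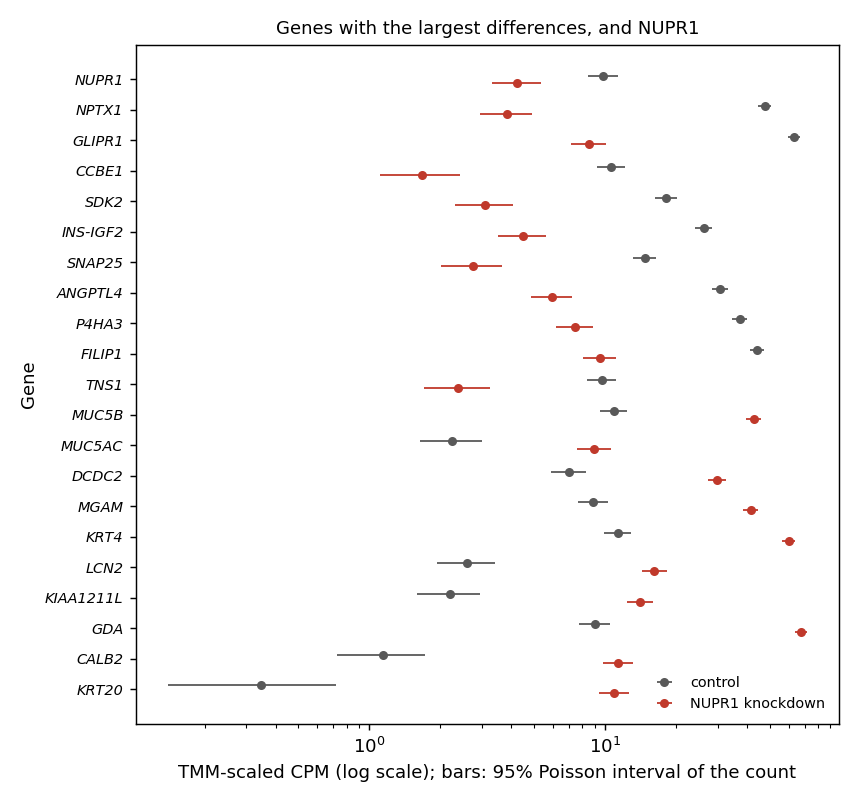
TMM-scaled CPM (horizontal axis, log scale) of NUPR1 and of the 10 genes with the largest ratio in each direction, in the control column (grey) and the NUPR1 knockdown column (red). Points are the single value per group and bars its 95% Poisson interval; the intervals of NUPR1 (3.30 to 5.33 and 8.48 to 11.3 CPM) do not overlap, and KRT20 has the widest bar, from 7 control reads.

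Gene lists fixed before the data were examined were compared by their median log2 ratio with 10000 random lists matched on size and mean expression. Of 28 lists with at least 5 measured members, 11 had a median above the middle 95% of the random lists, 2 below it and 15 inside it, where chance alone would put about 1.4 outside if genes varied independently. Genes of a pathway vary together, which the random lists do not carry, so a percentile describes these columns and is no p-value.

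Genes of mesenchymal transition and extracellular matrix had the lowest median of all 28 lists. Of 47 measured, 38 were lower in the knockdown column and 9 higher, 23 were at least 1.5-fold lower and 3 at least 1.5-fold higher. The median log2 ratio was -0.51, and 0 of 10000 random lists had one as low (middle 95% from -0.11 to 0.10). The median was -0.77 where at least 5 CPM was required in both columns and -0.34 with RPKM plus 1, below the random range in both settings. COL1A1, a chain of type I collagen, had a log2 ratio of -1.74 (-2.09 to -1.41) at 5.54 CPM against 18.6 CPM. CDH2, which encodes N-cadherin, had -1.65 (-1.96 to -1.35), and the matricellular gene CTGF -1.34 (-1.60 to -1.10). Immediate early genes were the other list below the range, with 21 of 29 lower, 7 of them by at least 1.5-fold, a median of -0.41 and 0 random lists as low. JUNB had -1.52 (-1.76 to -1.28), and the orphan nuclear receptors NR4A3 and NR4A1 had -1.11 and -1.05. DUSP5, a phosphatase that acts on ERK, went the other way at 1.30 (1.14 to 1.46). With RPKM plus 1 the immediate early median was -0.25, still below its range, and COL1A1 had -1.08.

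Lysosomal genes were shifted toward higher levels by a smaller amount. Among lysosomal hydrolases and membrane proteins, 41 of 59 were higher, 9 of them by at least 1.5-fold, and 0 were lower by as much. The median of the lysosome list was 0.18, and 0 of 10000 random lists had one as high. CTSS, a cysteine cathepsin, had a log2 ratio of 1.38 (0.96 to 1.81), SLC17A5, the lysosomal sialic acid exporter, 1.16 (0.88 to 1.45), and SMPD1 and CTSA had 0.96 each. Subunits of the vacuolar proton pump were higher in 15 of 20, with a median of 0.20 at percentile 99.6. Its subunit gene ATP6V0A1 had 1.05 (0.93 to 1.18) and ATP6V1C1 0.73, while ATP6V1E2 had -0.40. Genes of autophagosome formation divided 26 to 20, with a median of 0.12 at percentile 99.1. In that list the cargo receptor gene SQSTM1 had 907 CPM (892 to 921) against 419 CPM (411 to 429), a log2 ratio of 1.11, whereas ATG2A had 0.58 and WIPI1 0.52, and ATG16L1 had -0.46. Genes for tethering and reformation of late endosomes and lysosomes had a median of 0.10 inside the random range (percentile 95.4), with 25 of 39 higher, RAB27A at 0.73 and C17orf59 at 0.63. That median was 0.11, above its range, with the trend on gene length removed.

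The SNARE fusion machinery, the class to which SNAP25 belongs, did not stand apart as a list. Of its 44 genes 18 were higher and 26 lower, with a median of -0.03 at percentile 24.2 and a mean of 0.02, so that median and mean differ in sign. SNAP25 was the only member of this list at least 1.5-fold lower, and 5 were at least 1.5-fold higher, STX3 among them with 0.82 (0.60 to 1.04). Genes of neuronal exocytosis and neuron markers divided evenly, 13 higher and 12 lower, with 5 at least 1.5-fold in each direction. Their median of 0.26 lay at percentile 99.9. But it was 0.12, inside the range, with the control column thinned to the knockdown depth in a single random draw. The median was 0.07 with RPKM plus 1, also inside, and turned to -0.10 with no filter on low counts. NRCAM, a neural adhesion molecule, had 194 CPM (188 to 201) against 72.9 CPM (69.2 to 76.7), a log2 ratio of 1.41. CPLX2, a complexin that binds SNARE complexes, had 1190 CPM against 508 CPM, a log2 ratio of 1.23. SYN2 and NEFL had 0.80 and 0.71.

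Cholesterol synthesis and uptake gave the highest median among the lists outside the range. Of 25 genes 22 were higher, 7 by at least 1.5-fold and 0 lower by as much, with a median of 0.42 and 0 random lists as high (middle 95% from -0.11 to 0.13). HMGCS1, which makes HMG-CoA for the mevalonate pathway, had 429 CPM (419 to 439) against 175 CPM (169 to 181), a log2 ratio of 1.30. IDI1 and CYP51A1, further enzymes of the pathway, had 0.89 and 0.72. The list of fatty acid synthesis and lipid storage did not share that shift, with 17 of 35 higher and a median of -0.05 (percentile 15.3), and GPAM and the desaturase gene SCD had -0.64 each.

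Targets of the antioxidant regulator NRF2 were higher in 28 of 37, with 6 at least 1.5-fold higher and 0 lower by as much. Their median was 0.21, with 0 random lists as high. GPX2, a glutathione peroxidase, had 210 CPM against 70.2 CPM, a log2 ratio of 1.58 (1.49 to 1.67), and the heme oxygenase gene HMOX1 had 1.39 (1.27 to 1.51). OSGIN1 and GCLM had 0.95 and 0.62. Metallothionein and iron-handling genes divided 9 to 6, with a median of 0.21 at percentile 99.1. LCN2 led them, MT1X and SLC39A10 had -0.59 and -0.56, and STEAP1 had 0.53. This list fell inside its random range with a median of 0.14 once a trend on GC content was removed, and with 0.0032 where at least 5 CPM was required in both columns.

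Proliferation genes were higher by small amounts. Of 46 genes of G1/S and DNA replication 34 were higher, with a median of 0.18 and 0 random lists as high. RRM2, a subunit of ribonucleotide reductase, had 0.81 (0.74 to 0.87), RFC3 0.61, CCNE2 0.56 and GINS4 -0.52. Of 43 genes of mitosis and G2/M 35 were higher, 0 of them by 1.5-fold, with a median of 0.11 at percentile 98.5. NUSAP1 and CDK1 had 0.42 each, NDC80 0.41 and BUB3 0.39. Genes of homologous recombination and crosslink repair were higher in 25 of 38, with a median of 0.14 at percentile 99.6, and BARD1, RPA2, EXO1 and MUS81 had 0.71, 0.48, 0.36 and -0.35. The p53 targets were higher in 27 of 37, with a median of 0.13 at percentile 99.0. Among them PLK3 and GADD45A had -0.71 and -0.70, and the pro-apoptotic genes BBC3 and FAS 0.66 and 0.65. With the GC trend removed, medians of the G2/M (0.06), repair (0.09) and p53 lists (0.09) fell inside their random ranges. The p53 list was outside in only 7 of 12 alternative settings, which include scalings that could not change its side.

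**Figure D3:**
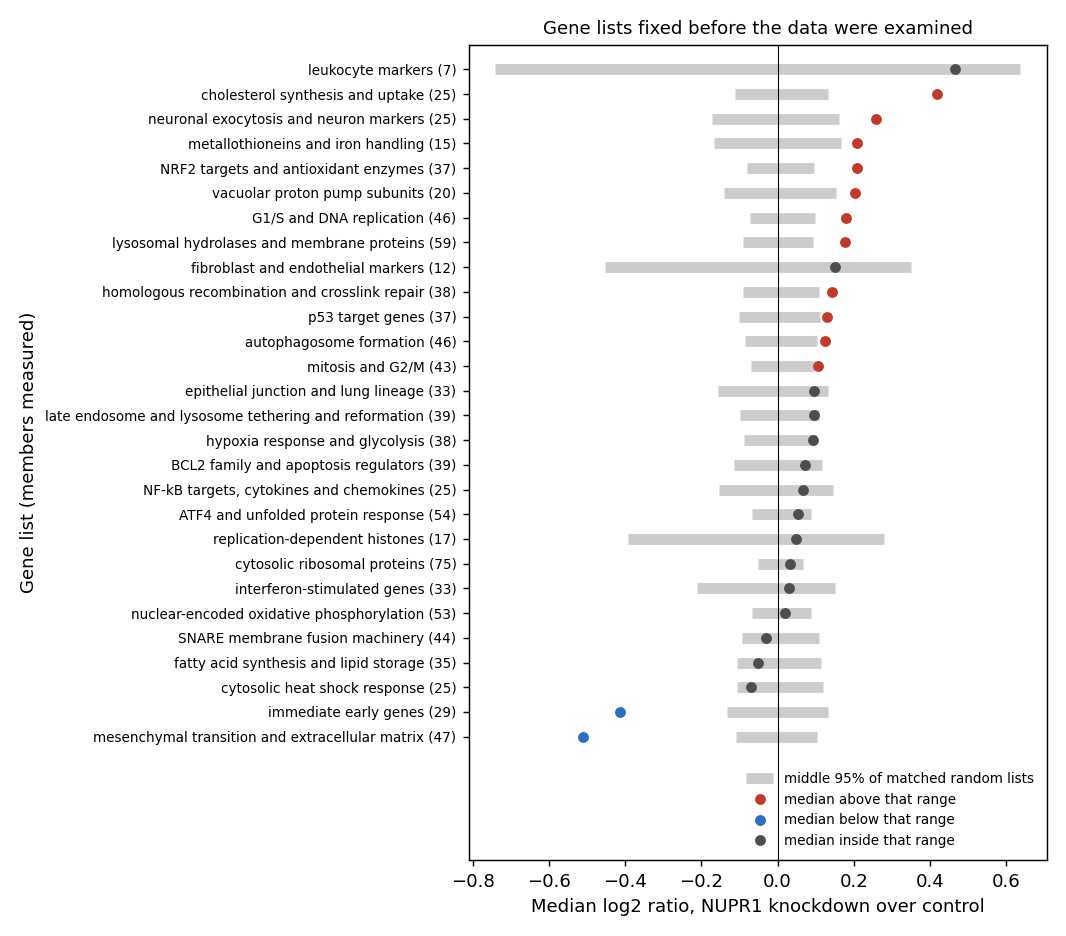
Median log2 ratio of NUPR1 knockdown over control (horizontal axis) for each of the 28 gene lists, with the number of measured members in brackets. Points are list medians and grey bars the middle 95% of medians of 10000 random lists matched on size and mean expression; 11 medians lie above their bar, 2 below (mesenchymal transition and immediate early genes) and 15 inside.

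The other lists lay inside their random ranges. Epithelial junction and lung lineage genes had a median of 0.10 (percentile 93.1), with 10 of 33 at least 1.5-fold higher, the mucins MUC5AC and MUC5B among them. That median was above its range at 0.18 with the GC trend removed and at 0.17 where at least 5 CPM was required in both columns. Hypoxia and glycolysis genes had 0.09 (96.5), with SLC2A3, a glucose transporter, at 1.62 and ANGPTL4 at -2.36. ATF4 and unfolded protein response genes had 0.05 (86.1), with KLHL24 at 1.32 and DDIT3 at 0.61. Apoptosis regulators had 0.07 (88.7), with CASP4 at 0.96 and BOK at -0.73. They lay above the range at 0.13 both with the GC trend removed and with the control column thinned to the knockdown depth. Heat shock genes had -0.07 (9.15), with HSPB1 at -0.74 and HSPD1 at -0.44. For 3 of these other lists the median and the mean differed in sign, as for the SNARE list above. These were interferon-stimulated genes at 0.03 and -0.03 (70.8), with IFI35 at 0.84 and GBP2 at -0.78, NF-kB targets at 0.07 and -0.09 (81.8), with BCL3 at -1.17 and PTGS2 at 0.76, and replication-dependent histones at 0.05 and -0.10 (70.0), with HIST1H2BD at -0.68 and HIST1H1C at -0.28. Histone transcripts lack poly(A) tails, and their near-identical copies make the counts of single genes uncertain. Cytosolic ribosomal proteins had 0.03 (73.8) with RPS21 at 0.60 and RPL10A at 0.31, and nuclear-encoded oxidative phosphorylation genes 0.02 (57.8) with SDHD at 0.48 and COX7A2 at 0.30.

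Most markers of leukocytes were too low to be measured. Of 24 listed with reads, 7 passed the filter, with a median of 0.47 inside a wide range of -0.74 to 0.64. CD68, which also encodes a lysosomal protein, had 34.3 CPM against 18.9 CPM, while PTPRC had 6 and 4 reads. Of 24 fibroblast and endothelial markers with reads, 12 were measured, 5 of them at least 1.5-fold higher and 2 at least 1.5-fold lower, with a median of 0.15 (percentile 82.9). Of this list the naming rule took COL1A1 at -1.74 and FBN1 at -0.28. With no filter on low counts the median was 0.48, above its range. COL3A1 had 27 reads in the knockdown column and 26 in the control column, DCN 12 and 6, and VWF 10 and 6, while LUM had 7 and 11, PDGFRB 3 and 5, THY1 5 and 6, and the red cell gene HBB 1 and 2.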

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

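A row named AD, which names no gene and has a deposited length of 1 base, was left out of the comparison because of that length, yet its reads differed between the columns. It held 14526 reads in the knockdown column and 10330 in the control column, 0.0872% and 0.0509% of all reads. After TMM scaling the ratio of knockdown to control was 1.683 (1.641 to 1.726), by counting error only. No biological explanation was tested, because the row cannot be tied to a gene from the table.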

How the results depend on the processing

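No paired analysis was possible because the tables hold 1 column per group. For the same reason the layout comparison, leaving out each library, the DESeq2, likelihood-ratio and limma tests, halved paired-end counts, the estimated correlation, the rotation test and the other prior count were not run. NUPR1 kept a log2 ratio between -1.04 and -1.23 in every alternative that gave it a value. With at least 5 CPM required in both columns NUPR1 and SNAP25 had none. KRT20, CALB2, KIAA1211L, LCN2, MUC5AC, NPTX1, CCBE1, SDK2, INS-IGF2 and TNS1, of the genes with the largest ratios, had none either. Each of these was under 5 CPM in 1 column. With RPKM plus a pseudocount of 1, 112 genes differed by 2-fold (57 higher, 55 lower) and SNAP25 stood at -1.72, because the pseudocount shrinks ratios of genes with a low RPKM. Long genes can have a low RPKM from many reads. The other thresholds, the removal of trends, leaving out rows without a symbol, the 10 expression bins, and all list settings except median-ratio scaling and the 5 CPM filter were chosen after seeing the data. The other thresholds gave 873 genes at 1.5-fold and 564 at a mean of 1 CPM, since both admit more genes. Other alternatives gave 172 to 236 genes. Of 1040 values of named genes under alternatives, 1010 stayed within their counting interval, 30 moved and 0 reversed. Of the 30, 25 were under RPKM plus 1. Changes of scaling alone moved every log2 ratio by 0.0274 or less, which lies within most intervals. Many of the 1010 were thus nearly fixed in advance. Of 41 named genes at least 2-fold apart, TNS1, CTSS, SLC17A5, ATP6V0A1, KLHL24, NR4A3 and NR4A1 fell under 2-fold with RPKM plus 1, NR4A3 and NR4A1 also with RPKM plus 0.1, and BCL3 and NR4A1 with the GC trend removed. Of 333 list values, 315 stayed on their side of the random range, 11 went inside it with the same sign and 6 went outside. The remaining 1, the neuronal exocytosis list with no filter on low counts, changed sign to -0.10 and also lay inside its range. That setting adds genes of few reads. The matrix, immediate early, cholesterol, lysosome, proton pump, autophagy, NRF2 and G1/S lists kept their side in all 12 settings, the p53 list in 7. These settings include the median-ratio, upper-quartile and total-count scalings. Such scalings move every list and its random lists by the same amount, so no list could change side under them.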

Other observations

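All tests in this part, the actin, TGF-beta and YAP lists and the genes named from them were chosen after the list ratios were seen; for GC content, what each outcome would show was written down before that test was run. Actin filament and focal adhesion genes, none of them in a fixed list, were lower in the knockdown column in 22 of 25 cases, 10 of them by at least 1.5-fold. Their median log2 ratio was -0.43, with 0 of 10000 matched random lists as low. FLNA, which crosslinks actin, had 935 CPM against 1822 CPM, and ZYX, a focal adhesion protein, had a log2 ratio of -1.10. CALD1, ACTN1 and VCL had -0.97, -0.81 and -0.79. TGF-beta responsive genes were lower in 21 of 23, with a median of -0.41 and 0 random lists as low, but 8 of its 25 members, 7 of them measured, stand in fixed lists, the matrix list among them. Without those, the TGF-beta list had 14 of 16 measured members lower and a median of -0.36, with 0 random lists as low. PMEPA1 and LTBP2 had -1.58 and -1.39, and TGFBI had -0.96, while SMAD7 and ID1 had -0.12 and -0.06. YAP and TEAD targets were lower in 16 of 21, with a smaller median of -0.16 at percentile 1.86, but 3 of them stand in fixed lists, and without these the median was -0.13, inside its random range (-0.15 to 0.14). ANKRD1, often used as a YAP target, went the other way at 1.78. These lists give no test of what lowers their members.

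For the lower matrix list, the median was -0.54 after the trend on GC content was removed and -0.49 after the trend on gene length, against -0.51 before. Over the measured genes these trends were small, with standard deviations of 0.075 and 0.021 in log2 ratio. Removing trends of that size could hardly bring the median into its random range. It is thus their small size that argues against them, and only as trends common to all genes. Fibroblasts in the control culture would bring their other abundant transcripts with COL1A1, but the summed reads of COL1A2, COL3A1, DCN and LUM were 65 in the knockdown column and 51 in the control column, a log2 ratio of 0.61 (0.06 to 1.17) where COL1A1 had -1.74. Among the causes that stay open are NUPR1 depletion itself and a difference in density or handling between the cultures. A different mix of single-end and paired-end reads in each column also stays open. With 1 column per group these cannot be separated, and the list is not complete.

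For the higher cholesterol list, the median was 0.41 after the GC trend was removed and 0.40 after the length trend, against 0.42 before. Here too both trends were small beside the median, and it is their size that argues against either as the whole cause. For the higher lysosome list, the corresponding medians were 0.18 and 0.20, against 0.18 before, and the length trend was small beside this median as well. For both lists NUPR1 depletion, a difference in medium or growth between the cultures and a different mix of layouts in each column stay open, as untested.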
